A study of Saccharomyces cerevisiae with 49 samples.

How the data were processed

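RNA from a continuous culture of strain CEN.PK113-7D was measured on 49 Affymetrix Yeast Genome 2.0 arrays, 1 array per sample, after oligo(dT)-primed amplification and biotin labelling, per the labels' protocols. The deposited values are probe-set signals, an intensity on a linear scale, which the authors made with GCOS, per the submitters' processing notes. Its version and settings are not given in the sources used here. The values carry no common scale: the trimmed mean ran from 2397 to 3924. The fixed design kept the scaling of the authors, so the values were used as deposited, and setting each array to the same median was run as an alternative and is printed where it changes a result.

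The table holds 10928 probe sets. The platform annotation gives 1 S. cerevisiae gene for 5498 of them (5449 genes), genes of another yeast species for 1746, several genes for 1, and no gene for 3683, which include 213 controls. Symbols were updated through the gene ID for 12. Probes were designed on a reference sequence and the strain is CEN.PK, so sequence differences of the strain can lower a signal. Probe sets of S. cerevisiae genes were tested where the median signal exceeded 11.2, the 75th percentile of the medians of the other-species probe sets, which left 5470 (5428 genes) and removed 28. Values under 1 were set to 1 and log2 was taken. The median signal of the S. cerevisiae probe sets was 1882 and that of the other-species probe sets 6.2. The number of arrays limits the precision.

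Samples were grouped by the phase angle of the labels. Cycling was tested with limma 3.58.1 in R 4.3.3 by the cosine and sine of the phase angle over 49 samples. Phase windows of 60 degrees were compared with the mean of the other 5 in the 47 samples of the first pass. The 2 samples of the second pass were compared with the first 2 samples. Each test used lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. "High" and "low" refer to this threshold, and fold is taken on the log2 scale of the signals. In the comparison of the passes eBayes gave every probe set the same spread, so its adjusted p-values are not printed.

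The 33 gene lists were written from textbook knowledge before the data were examined, as were the tests of the comparisons and all their alternatives except 4. The tests of technical explanations were written after the results were seen. Those 4 alternatives, chosen after the data were seen, were median scaling with an array number term, median scaling with the spread of the 2-harmonic fit, and the 8 arrays of phase 0-60 left out for the cycling probe sets and for the lists. The mean of a list was fitted with the cosine and sine of the phase angle and tested with 100000 permutations of the phase angles. The interval of its peak came from a bootstrap of residuals in blocks of 5 samples. Peak phases of called members were set against 10000 random lists of called genes matched on median signal. They lay closer together than in random lists except for glycolysis, gluconeogenesis, ergosterol biosynthesis, fatty acid synthesis, the pentose phosphate pathway and iron uptake, and alpha-specific genes were too few.

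The genes named were, for each window, the 4 with the largest difference above the other windows among those called for cycling and for that window, for each list the 2 called members with the largest fitted peak-to-trough ratio, and for the passes the 5 called with the largest difference. Not all of the genes that the rule names for the lists are printed. Where a gene had several probe sets, as 41 tested genes had, the one with the highest mean signal stood for it, and the calls of 7 such genes differed between their probe sets.

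The tests were tested on simulated data with 50 probe sets at each fold among 5470. The noise was drawn independently for each sample, and all but 200 probe sets were unchanged. The real series holds successive samples of 1 culture with most probe sets called, so these rates need not hold for it. As deposited, the cosine fit recovered 82% at 1.5-fold and 98% at 2-fold with 2 unchanged probe sets called, and the window fit 90% and 100% with 2. The comparison of the passes recovered 6% at 2-fold as deposited with 64 unchanged probe sets called, and 36% with median scaling with 3 called. Alternatives were quantile normalization, median scaling, other filters and offsets, 2 harmonics, terms in time and array number, subsets of the samples, a constant period and an intensity trend. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Gene neighbours and names came from a RefSeq gene table, and no coordinates are printed.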

Results

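The series followed a continuous culture of the haploid Saccharomyces cerevisiae strain CEN.PK113-7D, mating type a, while the culture oscillated with a period of about 4 h. Messenger RNA was measured on 49 Affymetrix Yeast Genome 2.0 arrays, 1 per sample, with a sample every 5 min. The labels give each sample a phase angle, from 244.11 degrees in the first sample to 614.63 degrees in the last, but not the event that defines phase 0. Samples were placed in 6 windows of 60 degrees, with 7 samples in phase 300-360 and 8 in each of the other 5 windows. A further 2 samples, at 606.97 and 614.63 degrees, lay in the next cycle and are called the second pass. The trimmed mean signal of the arrays ran from 2397 to 3924, a ratio of 1.64. Samples of a window were successive samples of 1 culture, so p-values measure the spread between such samples and not between cultures, and successive samples are not fully independent.

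Most of the measured transcriptome moved with the phase angle. Of 5470 probe sets of S. cerevisiae genes tested, 4268 (78.0%) followed a cosine of the phase angle, with a median fitted peak-to-trough ratio of 1.60 among them, and 1213 (22.2%) had a fitted ratio of at least 2-fold. HOF1, which acts in cytokinesis, fitted the cosine with a peak-to-trough log2 ratio of 3.96 (SE 0.10) and a peak at 180.8 degrees. CLB2, a mitotic cyclin, fitted with 3.62 (SE 0.14) and a peak at 158.1 degrees, and DSE4, a daughter-cell glucanase, with 4.12 (SE 0.24) and a peak at 268.7 degrees. DBP2, an RNA helicase of ribosome biogenesis, fitted with 3.81 (SE 0.50) and a peak at 354.4 degrees.

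The calls were made with limma's moderated F test and Benjamini-Hochberg adjustment on 49 samples. With each array set to the same median, 4838 probe sets were called, and 4216 were called under both scalings, whereas 331 to 1229 were called with 1 of every 3 samples. A cosine describes short pulses poorly, and the number with at least 2-fold was 2271 with 2 harmonics, 1992 with an F test over the windows and 616 without the 8 arrays of phase 0-60, an alternative chosen after the data were seen.

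**Figure D1:**
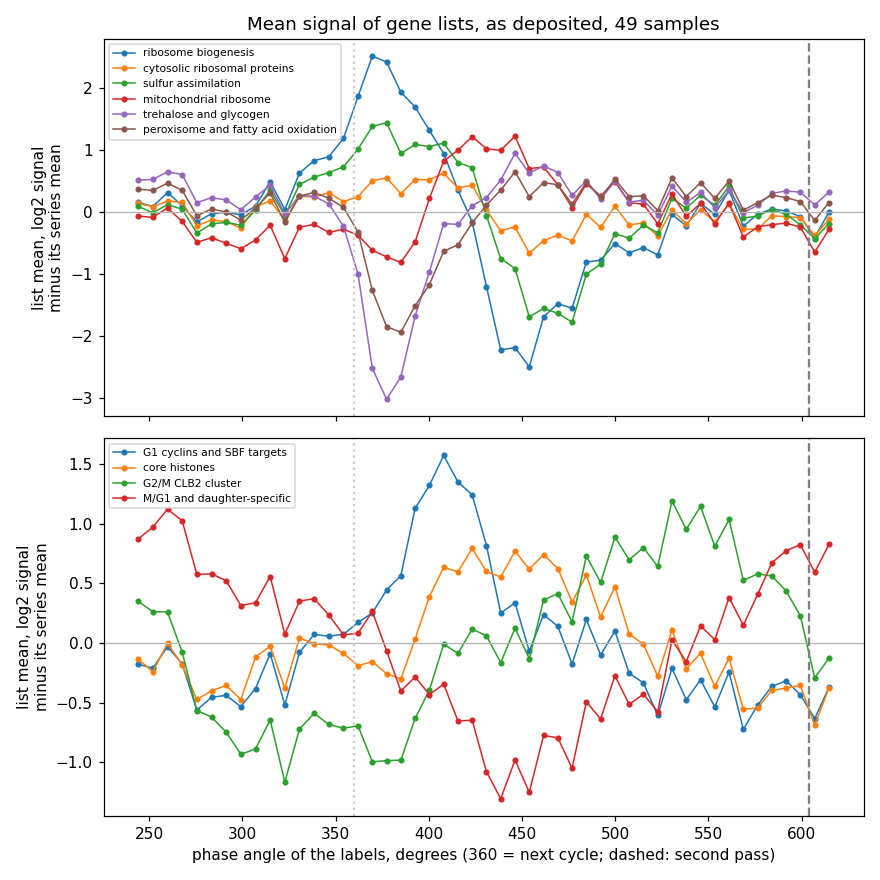
Mean log2 signal of 10 gene lists minus its mean over the series, against the phase angle of the labels in degrees, for the 49 samples. Each point is 1 array, the dotted line marks 360 degrees and the dashed line the start of the second pass. Ribosome biogenesis genes were high in phase 0-60 and low in phase 60-120, when storage carbohydrate genes went the opposite way.

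Phase 0-60 was the window in which genes for ribosome production and for the synthesis of amino acids and nucleotides were high and genes for storage carbohydrates, fat oxidation and stress were low. Of 116 ribosome biogenesis genes, 115 were high and 0 low, with a median 3.81-fold above the other windows. Of 20 genes for trehalose and glycogen, which are storage carbohydrates, 20 were low, with a median ratio of 0.269. DBP2 averaged 8316 ± 4350 (SD, n = 8) against a mean of 655.9 over the other windows, a log2 difference of 3.90 (SE 0.26, limma adjusted p = 8.39e-17).

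Other lists that were high in phase 0-60 were cytosolic ribosomal proteins, with 119 of 127 members and a median of 1.42-fold, RNA polymerases I and III, with 23 of 26 members high and 2 low, and aminoacyl-tRNA synthetases, with 17 of 18. Sulfur assimilation genes were high in 25 of 27 cases with a median of 2.53-fold, amino acid biosynthesis genes in 52 of 58 and purine and pyrimidine synthesis genes in 26 of 27 with 1 low. AAH1, adenine deaminase, had a log2 difference of 3.45 (SE 0.26), IMD4, an IMP dehydrogenase, 3.27 (SE 0.18), and ANS1 3.66 (SE 0.43). URA7, CTP synthase, averaged 6907 ± 3370 (SD, n = 8) in phase 0-60, 7.62-fold above the other windows, and LEU9, an isopropylmalate synthase, 4662 ± 1020 (SD, n = 8), 6.46-fold above them. HXT4, a glucose transporter, was 7.67-fold higher in phase 0-60, whereas 12 of the 16 glucose transport genes were low there.

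In the same window 41 of 48 genes of peroxisomes and fatty acid oxidation were low and 4 high, as were 26 of 30 autophagy genes with 0 high, 34 of 35 proteasome genes with 0 high and 22 of 28 heat shock genes with 1 high. Redox defence genes were low in 20 of 29 cases and high in 6, and gluconeogenesis, glyoxylate and acetate genes low in 17 of 23 and high in 3. Meiosis and sporulation genes were low in 20 of 29 cases and high in 4. POX1, acyl-CoA oxidase, averaged 1223 ± 1980 (SD, n = 8) in phase 0-60, its lowest window, and 13330 ± 1550 (SD, n = 8) in phase 120-180, its highest. TSL1, a subunit of trehalose synthase, averaged 2779 ± 2880 in phase 0-60 and 13790 ± 2840 in phase 60-120 (SD, n = 8 each). CTT1, cytosolic catalase, averaged 569.3 ± 703 (SD, n = 8) in phase 0-60 and 6643 ± 1250 (SD, n = 7) in phase 300-360.

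Over all genes, 2000 probe sets were high and 1993 low in phase 0-60 (limma, 47 samples, adjusted over 5470 probe sets), 664 and 618 of them by at least 2-fold. The large SDs of this window hold changes within it. The log2 ratio of 3' to 5' signal of control transcripts, a measure of RNA quality, averaged 0.316 ± 0.166 for TDH1 in phase 0-60 against 0.066 ± 0.071 on the other arrays (SD, n = 8 and 41, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted over 4 transcripts 4e-05), in a test chosen after the data were seen. It averaged 0.327 ± 0.130 against 0.227 ± 0.089 for ACT1 (adjusted p = 0.015), 1.098 ± 0.128 against 0.993 ± 0.085 for SPT15 (0.012) and 0.275 ± 0.123 against 0.218 ± 0.092 for RIP1 (0.14), with the same n. These permutations do not keep the order of successive samples.

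Phase 60-120 held the peak of genes for mitochondrial translation and of the core histones, while ribosome biogenesis genes were at their lowest. Of 71 mitochondrial ribosome genes, 70 were high and 0 low, with a median of 1.91-fold. All 7 core histone genes measured were high, with a median of 1.63-fold, and 115 of 116 ribosome biogenesis genes were low, with a median ratio of 0.243. HTB2, a histone H2B gene, averaged 16310 ± 2230 (SD, n = 8), 2.62-fold above the other windows.

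MRPL40 and MRPL8, of the large mitochondrial ribosomal subunit, were 2.28-fold and 2.30-fold higher in phase 60-120 than in the other windows. Tricarboxylic acid cycle genes were high in 12 of 18 cases and respiratory chain and ATP synthase genes in 19 of 40, with 0 low in either list. Of the 20 trehalose and glycogen genes 16 were high and 1 low. For these lists the other windows included the low phase 0-60, which raises the difference. The cosine peaks of the list means lay later, at 161.2 degrees for the tricarboxylic acid cycle, 154.9 for the respiratory chain and 193.7 for trehalose and glycogen. The cosine described these means poorly, with an R2 of 0.224, 0.259 and 0.268. With each array set to the same median, the smoothed means were highest within phase 60-120, at 101.6, 101.6 and 93.9 degrees. The genes with the largest differences were YJL213W (log2 difference 1.92, SE 0.21), MSF1, mitochondrial phenylalanyl-tRNA synthetase (1.72, SE 0.26), PLM2 (1.63, SE 0.22) and PET117, of cytochrome oxidase assembly (1.54, SE 0.24). In all, 1432 probe sets were high and 1330 low, 120 and 390 of them by at least 2-fold. With quantile normalization 2198 were high, with every second sample 864 or 428 were, and with a linear term in time 815 were low.

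Lists of cell division genes peaked at different phases. Of 28 G1 cyclins and SBF targets, 26 were high in phase 0-60 and 1 low, and of 55 DNA replication and G1/S genes 42 were high there and 1 low. Genes of the G2/M CLB2 cluster were high in phase 120-180 in 19 of 23 cases and in phase 180-240 in 16 of 23, with 0 low in either. M/G1 and daughter-specific genes were high in phase 240-300 in 16 of 25 cases with 0 low, and low in phase 60-120 in 22 of 25. The cosine peaks of the list means were 28.8 degrees for DNA replication and G1/S genes (95% block-bootstrap interval 354.2 to 66.6), 49.8 for the G1 cyclins and SBF targets (28.6 to 71.7), 83.6 for core histones (66.2 to 101.1), 165.8 for the CLB2 cluster (159.3 to 173.0) and 270.7 for the M/G1 genes (262.6 to 278.3). The G1 cyclins and SBF targets thus peaked 21 degrees after the DNA replication and G1/S genes (interval 2.7 to 43.3). These peaks came from the values as deposited. With each array set to the same median, the smoothed means of both lists were highest at 40.3 degrees. With a linear term in time, which shares variation with the windows, 0 members of any list stayed high in phase 120-180, 180-240, 240-300 or 300-360, although the list means named here still passed the cosine test. The log2 difference of HOF1 in phase 120-180 was then 2.049 (SE 0.508) instead of 1.992 (SE 0.196), and that of DSE4 in phase 240-300 1.189 (SE 1.188) instead of 2.185 (SE 0.297). The median SE over all probe sets rose from 0.115 to 0.293 in phase 120-180, 0.468 in 180-240 and 0.456 in 240-300, and from 0.121 to 0.296 in 300-360.

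PCL1, a G1 cyclin, was 3.79-fold higher in phase 0-60, where MCD1, a cohesin subunit, was 4.30-fold and CLB6, an S-phase cyclin, 4.24-fold higher. In phase 120-180, CLB2 averaged 1685 ± 259 (SD, n = 8), a log2 difference of 1.96 (SE 0.21), and CLB1, another mitotic cyclin, 4477 ± 657 (SD, n = 8), a difference of 1.87 (SE 0.21). HOF1 was 3.98-fold higher in phase 120-180 and 4.02-fold in phase 180-240, and YMR030W-A 4.61-fold and 7.54-fold. In phase 180-240 YNL058C was 3.98-fold higher, and HMLALPHA1, a gene of a silent mating-type locus, averaged 46.4 ± 14.6 (SD, n = 8) against 16.9, levels near the background of the array. In phase 240-300 DSE4 averaged 10210 ± 2290 (SD, n = 8), 4.55-fold above the other windows, and PRY3 was 3.97-fold, PCL9, an early G1 cyclin, 3.56-fold and DSE1 3.41-fold higher. In phase 300-360 YDL218W was 6.19-fold higher, GRE1, a stress-induced gene, 3.20-fold, PDC6, a pyruvate decarboxylase, 2.94-fold and MUP1, a methionine permease, 2.85-fold, although MUP1 averaged 3650 ± 1340 (SD, n = 7) there and 4961 ± 3910 (SD, n = 8) in phase 0-60, its highest window. Of the 116 ribosome biogenesis genes 88 were already high in phase 300-360.

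In phase 120-180, 365 probe sets were high and 585 low (38.4% high), in phase 180-240 82 and 62 (56.9% high), in phase 240-300 166 and 316 (34.4% high) and in phase 300-360 390 and 144 (73.0% high). The share of high calls depended on the scaling and was 55.7%, 46.6%, 47% and 40.5% with quantile normalization, and 47.6%, 53.9%, 50.4% and 47.9% with each array set to the same median, which called 2354, 804, 1583 and 1430 probe sets. With every second sample the high calls in phase 300-360 numbered 17 or 4, and with a linear term in time the high calls in these 4 windows numbered 0.

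**Figure D2:**
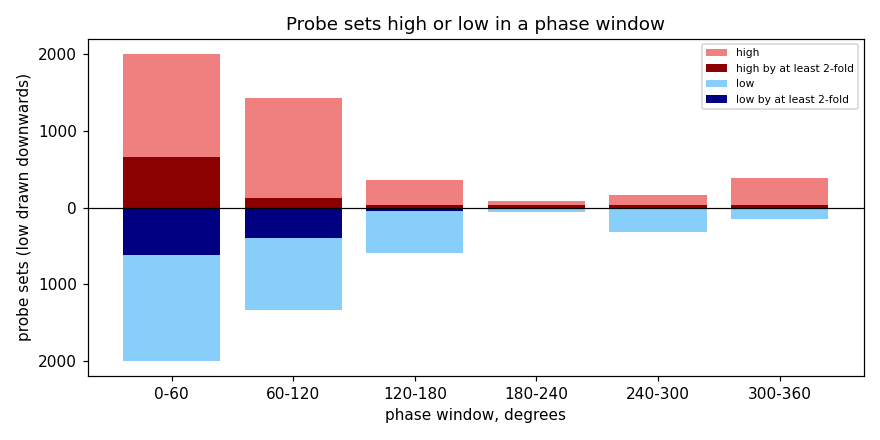
Number of probe sets high (upwards) or low (downwards) in each window of 60 degrees against the mean of the other 5 windows, with those that differ by at least 2-fold in the darker colour. Phase 0-60 had 2000 high and 1993 low probe sets and phase 180-240 had 82 and 62.

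In most gene lists the called members peaked closer together than in random lists, but not in glycolysis (adjusted p = 0.31), gluconeogenesis (0.11), ergosterol biosynthesis (0.47), fatty acid synthesis (0.42), the pentose phosphate pathway (0.54) and iron uptake (0.99), and alpha-specific genes were too few to test. The list mean followed the phase angle (permutation test, adjusted over 33 lists) in every list but glycolysis (adjusted p = 0.25), ergosterol biosynthesis (0.11), fatty acid synthesis (0.16) and iron uptake (0.92). The permutations do not keep the order of successive samples, so a smooth drift over the single cycle could also pass. The R2 of the list mean was 0.889 for the M/G1 genes, 0.885 for the CLB2 cluster, 0.696 for core histones and 0.519 for the mitochondrial ribosome, but 0.380 for ribosome biogenesis. With each array set to the same median, the smoothed mean of ribosome biogenesis ranged 27.7-fold from its maximum at 17.4 degrees to its minimum at 86.2 degrees. Ribosomal protein genes have near-identical copies, as do histone genes, so single members of these families are uncertain. Without the 8 arrays of phase 0-60, chosen after the data were seen, the list mean no longer passed for aminoacyl-tRNA synthetases, amino acid biosynthesis, heat shock proteins, trehalose and glycogen, autophagy, gluconeogenesis, glucose transport, redox defence, the pentose phosphate pathway and meiosis and sporulation.

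The counts of members called as cycling stand beside the 78.0% called over all probe sets tested. Members called as cycling numbered 116 of 127 for cytosolic ribosomal proteins, 116 of 116 for ribosome biogenesis, 25 of 26 for RNA polymerases I and III, 18 of 18 for aminoacyl-tRNA synthetases, 49 of 58 for amino acid biosynthesis, 24 of 27 for sulfur assimilation and 25 of 27 for purine and pyrimidine synthesis. They numbered 71 of 71 for the mitochondrial ribosome, 37 of 40 for the respiratory chain and 15 of 18 for the tricarboxylic acid cycle. For the cell division lists they were 7 of 7 core histones, 50 of 55 DNA replication and G1/S genes, 27 of 28 SBF targets, 23 of 23 genes of the CLB2 cluster and 23 of 25 M/G1 genes. Among stress and degradation lists 29 of 35 proteasome, 21 of 28 heat shock, 43 of 48 peroxisome, 20 of 20 trehalose and glycogen, 24 of 30 autophagy and 27 of 29 redox defence genes were called. Among lists of carbon metabolism 10 of 24 glycolysis, 18 of 23 gluconeogenesis, 12 of 16 glucose transport and 11 of 13 pentose phosphate genes were called, and among the others 21 of 26 ergosterol, 12 of 15 fatty acid synthesis, 11 of 18 vacuolar ATPase and 14 of 20 iron uptake genes. Adjusted over the list alone the count was 119 for cytosolic ribosomal proteins, 50 for amino acid biosynthesis, 16 for the tricarboxylic acid cycle, 44 for peroxisomes, 9 for glycolysis, 19 for gluconeogenesis and 24 for meiosis and sporulation, and the count over all genes in the other lists.

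In the 4 lists whose mean did not pass, single members were still called. Of 24 glycolysis genes 2 were high and 14 low in phase 0-60, and of 20 iron uptake genes 5 were high and 8 low. ERG4, of ergosterol synthesis, was 3.13-fold higher in phase 0-60, where 8 members were high and 9 low. ELO2 and ELO3, fatty acid elongases, were 2.52-fold and 2.65-fold higher there, with 3 members high and 5 low. FET4, a low-affinity iron transporter, was 3.30-fold higher in phase 0-60, and HMX1, heme oxygenase, was 1.47-fold higher in phase 180-240. With each array set to the same median the list means of glycolysis (R2 0.234), ergosterol biosynthesis (0.596) and iron uptake (0.177) passed the test.

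Markers of mating type and of sporulation also moved, as did reference genes. Of all probe sets tested 78.0% were called as cycling, so a count near that share does not set a list apart. Of 7 a-specific genes, expressed in cells of this mating type, 6 were called and 6 were high in phase 0-60, BAR1, the protease that degrades alpha factor, by 2.34-fold. Of 5 alpha-specific genes 3 were called, and 2 were high and 1 low in phase 0-60, with a median of 1.04-fold. Among them MF(ALPHA)1, an alpha-factor gene, averaged 1636 ± 399 (SD, n = 8) in phase 0-60 and 139.3 ± 47.1 (SD, n = 8) in phase 120-180. Of 29 meiosis and sporulation genes 23 were called, and SPS100, a spore wall gene, was 2.57-fold higher in phase 300-360. Of 10 reference genes often taken as constant 8 were called, and TUB2, beta-tubulin, averaged 10640 ± 1150 (SD, n = 8) in phase 60-120, 1.56-fold above the other windows.

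The second pass addressed whether transcripts returned to their levels after a cycle. After each array was set to the same median, 98.8% of the 5470 probe sets were within 1.5-fold of the first 2 samples of the series, which lie at the nearest phase angles. The median absolute log2 difference between the passes was then 0.088, against 0.094 between neighbouring samples and 0.316 between samples on opposite sides of the cycle. As deposited these 3 values were 0.329, 0.236 and 0.370, so the result depends on the scaling. The second pass as deposited was dimmer by a median log2 difference of -0.33, and limma called 36 probe sets, 12 higher and 24 lower. With median scaling limma called 0 of the 5470.

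The 5 called genes with the largest differences had signals near the background of the array. PFS1 averaged 4.2 in the first and 17.0 in the second pass, YLR012C 19.9 and 6.2, YLR412C-A 9.0 and 19.6, FYV12 11.4 and 3.65 and AZR1 23.2 and 9.85. An unadjusted p under 0.05 was found for 664 probe sets as deposited. With n = 2 in each pass the comparison recovered 36% of simulated 2-fold changes with median scaling. As deposited it recovered 6% and called 64 unchanged simulated probe sets, more than the 36 called in the real data. The count was 4910 without second pass replicate 2, 0 without second pass replicate 1 and 15 without replicate 1 of phase 240-300.

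**Figure D3:**
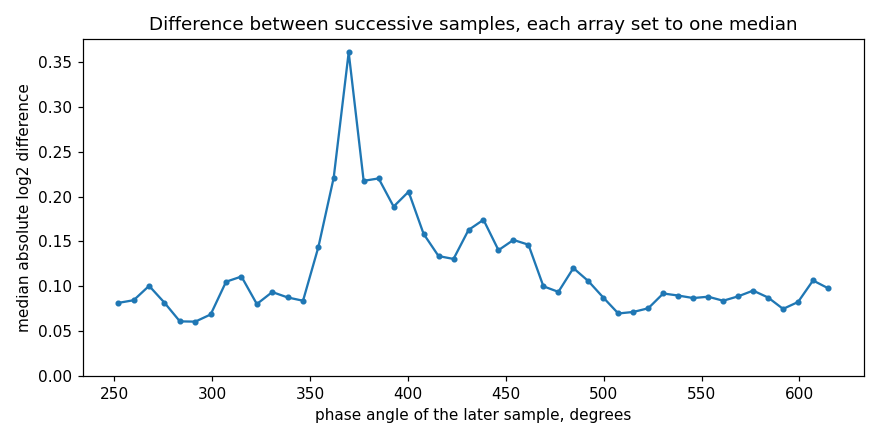
Median absolute log2 difference over 5470 probe sets between successive samples, each array set to the same median, against the phase angle of the later sample in degrees. The highest value, 0.361, was reached between 362.04 and 369.7 degrees, where 418 probe sets differed by at least 2-fold.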

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

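The tests by reassigned phases, of the change near phase 0 and of the ribosomal RNA signal were written down only after their results had been seen. Among 246 sets of 7 or 8 samples examined for 1 sample far from the others, 2 had such a sample, fewer than the 12.3 that chance gives. Both lay on the array at 322.77 degrees. Core histones averaged -0.38 there against -0.04 on the other arrays of phase 300-360, with a gap of 0.621 of the range. The a-specific genes averaged -0.36 against 0.09, with a gap of 0.639 of the range. This array was the dimmest of the window, with a trimmed mean of 2486 against 2886 to 3373, and 31 of the 33 lists were lowest on it. After each array was set to the same median 0 of the 33 were, and core histones stood at -0.05 against -0.14 and the a-specific genes at -0.03 against -0.01, so both low values went with the brightness of the array.

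With the phase angles reassigned at random over the samples, 1 of 100 assignments, the real one, gave as many cycling probe sets, with 4268 in the real order and at most 0 in the others. For probe sets high or low in any window it was also 1 of 100, with 4622 against at most 3037 and a median of 0 in the others. Chance is excluded only in the sense of a random arrangement of the samples. The reassignment does not keep the order of successive samples, so a smooth drift over the single cycle is not excluded by it, and with a linear term in time 4310 cycling probe sets were called.

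The largest change of the whole transcriptome between successive samples lay between 354.23 and 17.35 degrees. The closest pair of arrays before and after it differed by a median of 0.343, against at most 0.174 between neighbours outside phase 0-60. That pair lay several sampling steps apart, so this comparison does not decide on a single faulty array. The successive steps from 354.23 to 40.31 degrees were 0.221, 0.361, 0.218, 0.220, 0.189 and 0.205. A single array takes part only in the step into it and the step out of it, so 1 faulty array could not give all of these. The difference between neighbours did not grow with the gap in array number (Spearman rho -0.321, permutation p = 0.027, the opposite direction). The labels do not say that this number is an order of processing, so the order of the arrays stays open. RNA quality stays open: the 3' to 5' ratios of 4 control transcripts lay on average 0.268, 0.304, 0.667 and 1.912 SD above the other arrays at 354.23, 2.04, 9.7 and 17.35 degrees, under the 2 SD set for a cause, but single ratios lay up to 4.029 SD from them (ACT1 at 17.35 degrees), past the 1 SD set against it. A change of the culture at this phase was not separated from it.

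The 16 control probe sets for ribosomal RNA, which no comparison used, were higher in phase 0-60 than on the other 41 arrays by 1.01 on the log2 scale (SD 0.93 in phase 0-60 and 0.49 elsewhere, permutation p = 0.00021). Within phase 0-60 replicates 4, 5 and 6, with array numbers 17, 36 and 24, stood at 1.76, 1.84 and 1.93. Replicate numbers follow the order of sampling, so these were successive samples, after 17.35 degrees and up to 40.31 degrees. Replicate 3, at 17.35 degrees, stood at -0.37, and replicates 1, 2 and 7 at -0.07, 0.08 and 0.49. Replicate 8, at 55.62 degrees, stood at 1.095, while the highest array outside the window stood at 0.94. The brightness of the arrays is argued against by a difference of 0.977 after median scaling. A lower share of mRNA would raise poly-A spike-ins alike, and the mean rise exceeded that of the spike-ins by 0.804 (permutation p = 0.0001). The permutations for the ribosomal RNA signal do not keep the order of successive samples, so their p-values can overstate the evidence. Relative to the array median the spike-ins stood at -1.34, -1.58 and -1.89 on replicates 4, 5 and 6. On the other arrays of the window they stood at -2.75 to -2.02. A lower share of mRNA is thus argued against as the whole of the rise, but stays open as a part of it. RNA quality, more ribosomal RNA carried into the labelling, or more polyadenylated or precursor ribosomal RNA in the cells, was not tested for this signal and stays open.

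Among 3470 probe sets that the annotation does not name, 437 exceeded the 95th percentile of the other-species probe sets, and 72 of these cycled, 50 by at least 2-fold. Of 1746 other-species probe sets 88 exceeded that level, a count that its definition fixes, and 0 of those cycled (limma, 3 calls at any level).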

How the results depend on the processing

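The alternatives with phase 0-60 left out and with median scaling and the spread of the 2-harmonic fit were chosen after the data were seen. Over all counts and list results 631 of 748 values under an alternative stayed within 1.5 times of the value as reported or on the same side of the threshold. Of the others, 11 list means lost their call, 6 gained one and 100 counts moved. These values carry no direction that could reverse. Of 1422 values for named genes 0 reversed, which only window and pass differences could do, since a peak-to-trough ratio has no sign. Of these values 1247 kept their side of the threshold and 175 lost it, most with 1 of every 3 samples. Fewer samples lower the power by construction, and in the other cases the cause was not tested. Signals near background limit the low genes.

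With 1 of every 3 samples the cycling probe sets numbered 486, 1229 and 331, and those with at least 2-fold 422, 631 and 267. Those with at least 2-fold numbered 2271 with 2 harmonics, 1992 with the F test over the 6 windows and 616 without phase 0-60.

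With quantile normalization the high calls were 2198 in phase 60-120, 1491 in 120-180, 595 in 180-240, 880 in 240-300 and 767 in 300-360, and the low calls of the last 4 were 1187, 683, 992 and 1128. With median scaling the high calls of those 4 were 1121, 433, 798 and 685 and the low calls 1233, 371, 785 and 745. With an array number term 640 were high in phase 120-180 and 236 low in 300-360. With log2(signal + 16), 12 were low by at least 2-fold in phase 240-300, and with the second pass added 692 were low there.

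With a linear time term 815 were low in phase 60-120. In phase 120-180, 180-240 and 240-300 the high and low calls, and those by at least 2-fold, were all 0. In phase 300-360 the high calls were 0, as were those by at least 2-fold, and the low calls 3, all 3 by at least 2-fold. The windows follow one another in time, so this term shares variation with them.

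With every second sample, first series, phase 60-120 had 864 high and 829 low, phase 120-180 23 and 60 (19 and 30 by at least 2-fold), phase 180-240 17 and 10 (14 high by at least 2-fold), phase 240-300 37 and 15 (7 low by at least 2-fold) and phase 300-360 17 and 24 (6 high by at least 2-fold). In the second series phase 60-120 had 428 high, phase 120-180 56 and 38 (23 low by at least 2-fold), phase 180-240 30 and 11, phase 240-300 21 and 48 (16 high by at least 2-fold) and phase 300-360 4 and 9 (1 high and 9 low by at least 2-fold).

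The return after a cycle called 0 with quantile normalization, with median scaling, with the spread of the 2-harmonic fit and with both of the last together, 21 with log2(signal + 16) and 3855 with 4 first-pass samples. Leaving out 1 of the 4 samples gave 0 to 4910, and a lone sample is then assumed to vary like the other pair. With the samples of the nearest phase angles taken as pairs, which here share a replicate number, the count was 30.

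Without phase 0-60 the members called were 61 for cytosolic ribosomal proteins, 4 for aminoacyl-tRNA synthetases, 16 for purine and pyrimidine synthesis, 18 for the proteasome, 8 for heat shock, 28 for peroxisomes, 12 for trehalose and glycogen, 9 for autophagy, 6 for glycolysis, 5 for glucose transport, 11 for redox defence, 7 for the pentose phosphate pathway, 7 for the vacuolar ATPase and 5 for reference genes. The list mean then lost its call for aminoacyl-tRNA synthetases (R2 0.083), amino acid biosynthesis (0.147), heat shock (0.012), trehalose and glycogen (0.072), autophagy (0.002), gluconeogenesis (0.078), glucose transport (0.019), redox defence (0.035), the pentose phosphate pathway (0.145) and meiosis and sporulation (0.096). Glucose transport also lost it with no filter (R2 0.122). Glycolysis gained a call with quantile normalization (R2 0.376, with 18 members), median scaling (0.234) and a time term (0.139, with 17 members), ergosterol biosynthesis with quantile normalization (0.534) and median scaling (0.596), and iron uptake with median scaling (0.177).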

Other observations

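Many transcripts fell or rose within 15 min. Among 5021 probe sets that started at a signal of at least 500, 589 fell at least 4-fold over 15 min and 22 at least 16-fold. Of the 589 falls 281 started from a sample in phase 300-360 and 258 from one in phase 0-60. Falls and rises are placed by the first sample of the 15 min, so those counted in phase 300-360 could run into phase 0-60. After median scaling, 22 probe sets differed at least 2-fold between 346.37 and 354.23 degrees, and 195 between 354.23 and 2.04 degrees. Among 5011 that ended at such a signal, 359 rose at least 4-fold, 155 of them from phase 300-360 and 164 from phase 0-60. These genes were chosen after their values were seen. ANS1 rose from 138.2 at 346.37 degrees to 4493 at 9.7 degrees and fell from 4326 at 17.35 degrees to 135.4 at 40.31 degrees. PXA2, a subunit of the peroxisomal fatty acid importer, fell from 3274 to 88.0 between 354.23 and 17.35 degrees, which corresponds to a halving every 3.13 min after median scaling. FOX2, of fatty acid oxidation, rose from 771.9 at 55.62 degrees to 12488 at 78.58 degrees.

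The brightness of the arrays fell with the array number of the labels (Pearson r = -0.526, permutation p = 0.0001, adjusted 0.0002; Spearman rho = -0.517, permutation p = 0.0002, adjusted 0.0004; r = -0.522 without the 2 most extreme arrays). It followed the hybridisation spike-ins (r = 0.710, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 4e-05; rho = 0.685, p = 1e-05, adjusted 4e-05; r = 0.671 without the 2 most extreme). With the cosine of the phase angle r was 0.056 (permutation p = 0.70; rho 0.023, p = 0.88), and with its sine 0.192 (permutation p = 0.19; rho 0.199, p = 0.17). These were 4 relations over 49 arrays. The labels do not say that the array number is an order of processing.

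A hypothesis written before its result was seen was that neighbouring genes share transcription and so peak at similar phases. Over 3905 pairs of neighbouring cycling genes that do not overlap, the median difference in peak phase was 80.5 degrees, against 90.1 in shuffled genes (permutation p = 0.0005, the smallest that 2000 shuffles can give). By orientation it was 66.3 degrees for 1015 divergent pairs (adjusted p = 0.00067), 82.2 for 1863 tandem pairs (adjusted p = 0.00067) and 93.6 for 1027 convergent pairs (adjusted p = 0.87). The difference between orientations was not tested. The values are consistent with shared promoter regions of divergent genes, but related genes lying side by side could give the same and were not separated.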
